A study of Homo sapiens with 18 samples.

How the data were processed

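Total RNA from 18 HCT-8 cultures was extracted with Trizol, and 100 ng of each was labelled with biotin by poly-A primed in vitro transcription for a 3' Affymetrix PrimeView array, 1 array per culture. The cultures form 6 groups of 3 biological replicates: parental cells and their 5-FU-induced resistant derivative, each at 0, 24 and 48 h of 5-FU. The dose and the drug status of the resistant line before the experiment are not known here. The deposited values are log2 intensities, made by the authors with RMA (background correction, quantile normalization of probes and median polish per probe set) per the labels, which give no software version. The values bear this out, running from 0.56 to 13.68 with array medians between 4.57 and 4.64. Because RMA equalises the arrays, every change is relative to the rest of the array. ERCC spike-in RNA was added by cell number, per the labels, but no ERCC probe set is among the values used, so RNA content per cell was not analysed here.

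Of 49395 probe sets, 46826 carry a gene name, 44994 of them a single symbol, and 1832 several. The gene names of 44967 single-symbol probe sets were updated by gene ID, and 27 kept the platform's name. The 2569 probe sets not named here, 102 of them array controls, and those with several symbols were left out of the tests. Each gene was read by its single-symbol probe set with the highest mean over the 18 arrays, which gave 18132 genes, and 11735 of them (64.7%) had more than 1 probe set to choose from. No filter on dim genes was used.

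A linear model with 1 coefficient per group was fitted to all 18 arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, default settings, statmod 1.5.0). From it came 11 contrasts: resistant against parental at each time, 24 h and 48 h against 0 h and 48 h against 24 h in each line, and the difference between the lines' responses at 24 h and 48 h. Genes with a Benjamini-Hochberg adjusted p below 0.05 within a contrast were counted, with those of an absolute log2 change of at least 1 beside them. All p values are two-sided. The share of genes whose groups of arrays did not overlap was counted as well.

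For the list tests, 31 gene lists were fixed: 5-FU uptake, activation and breakdown, the thymidylate and folate cycle, p53 targets, G1/S and DNA replication, G2/M and mitosis, histone genes, base excision and mismatch repair, homologous recombination and Fanconi genes, the BCL2 family, death receptors and caspases, ABC drug efflux transporters, NRF2 and glutathione, the integrated stress response, ER chaperones, NF-kB targets, interferon-stimulated genes, MHC class I antigen presentation, epithelial junction and keratin genes, mesenchymal genes, stem cell and Wnt targets, intestinal differentiation genes, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, hypoxia and glycolysis, cholesterol synthesis, autophagy and lysosome, immediate early genes, cancer-testis antigens, and markers of leukocytes and of fibroblasts and endothelium. Each was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 31 lists within a contrast. Beside it stand camera with an estimated correlation and fry, which asks only whether a list moves on balance 1 way. Of 130 calls by camera over the 11 contrasts 48 held with an estimated correlation. List results in the Results section that lost their call show that p, while the closing sections give some list values without it. Some genes sit on more than 1 list.

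The contrasts, lists, alternatives and rule for named genes were chosen before the data were examined. The rule takes the 8 largest rises and the 8 largest falls with an adjusted p below 0.05 and no overlap between the arrays for the untreated lines and for each line at 24 h and 48 h against 0 h, and 4 each way for the other contrasts. For a difference of responses it takes adjusted p and size alone. To these it adds members of a list where that list is described, first those with the largest change, and TYMS, TYMP, UMPS, UPP1, DPYD, TK1, RRM2, CDKN1A, MDM2 and ABCB1 whatever their values. XIST, genes of the Y chromosome and probe sets with no symbol or several are not named.

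The pipeline was tested on simulated data of 18132 genes with the spread of these arrays. For the untreated lines, 76% of genes with a simulated log2 change of 0.5 and 99% of those with 1 were called, with 12 false calls among 187. For the difference of responses at 24 h these shares were 33% and 87%, with 4 false calls among 124, and every called gene had the right sign. A shift of 0.3 in the p53 list was called with 0 other lists. The simulated genes were drawn independently of each other, while in the arrays 1 component held 30.1% of the variance within groups. The simulation therefore does not test the list calls under correlation between genes.

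Alternatives were centring each array on its median, quantile normalization between arrays, leaving out the lowest 25% or 50% of genes by mean, the mean of all probe sets of a gene, each probe set tested alone, a replicate block, a fit of the compared groups alone, eBayes with trend and robust, an adjusted p below 0.01, and leaving out each array in turn. A correction for the main component of the deviations within groups, scored on the 25% of genes with the lowest mean, and list tests without parental 0 h replicate 2 were added after seeing the data. Array level checks covered the Alu, ACTB, GAPDH, 18S, poly-A and BioB control probe sets. Counts over other splits of the arrays used all 10 splits of 6 arrays, or 100 drawn relabellings of the lines within each time, as planned and with the lines' mean difference over the 2 times taken out first.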

Results

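HCT-8 is an established human colorectal adenocarcinoma cell line. Parental HCT-8 cells and a derivative selected for resistance to 5-fluorouracil (5-FU), a fluorinated pyrimidine that blocks thymidylate synthase and is built into RNA and DNA, were profiled on expression arrays. Both lines were sampled untreated (0 h) and after 24 h and 48 h of 5-FU. Untreated here means before this exposure, since earlier drug contact of the resistant line is not known here. No drug-free culture at 24 h or 48 h is among the samples. A change called a response to 5-FU therefore cannot be told apart from an effect of time in culture. Each of the 6 groups held 3 biological replicates, which makes 18 arrays, and this number limits the precision. Each array gave log2 values for 49395 probe sets, and 18132 genes were tested. Array medians lay between 4.57 and 4.64, so that the values show abundance relative to the rest of the same array and not the amount of RNA per cell. Changes below are log2 differences ± SE of the fitted model, with 3 arrays per group unless another number is given.

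Several control signals moved with the cell line. The control probe set for Alu repeats read 13.43 to 13.52 on the 9 resistant arrays and 13.02 to 13.42 on the 9 parental arrays. The 3' minus 5' difference of the ACTB control probe sets was 1.91 ± 0.17 (SD, n = 9) in the resistant line and 1.60 ± 0.17 (SD, n = 9) in the parental line. That of GAPDH went the other way, at -0.097 ± 0.033 in the resistant and -0.0027 ± 0.021 in the parental line (SD, n = 9 each). The 18S ribosomal RNA control was lower in the resistant line, at 10.87 ± 0.27 against 11.43 ± 0.16 (SD, n = 9 each). The bacterial poly-A controls, added before labelling, averaged 5.39 ± 0.13 in the resistant and 5.90 ± 0.12 in the parental line (SD, n = 9 each). They ran from 5.18 to 5.52 and from 5.72 to 6.08, without overlap. These controls do not come from the cells. How far differences between the lines follow RNA input or labelling therefore cannot be told here.

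The comparison of the untreated lines asks how the resistant cells differed before the exposure measured here. Only 1 resistant derivative was profiled, so the p values measure the spread between cultures of the same line. A difference tied to resistance cannot be told apart from any other difference between these 2 lines. Genes for histones H2B and H2A were among the most increased in the resistant line, with H2BC5 higher by 3.36 ± 0.08, H2BC12 by 2.90 ± 0.10, and H2AC6 by 2.78 ± 0.10. H2BC21 was higher by 2.77 ± 0.11, with the same sign in 1 of its 3 probe sets. TRIM22, a gene induced by p53 and by interferon, was higher by 3.14 ± 0.11, the aldehyde dehydrogenase ALDH1A1 by 2.51 ± 0.19 and the lysozyme gene LYZ by 2.47 ± 0.11. MYH4, a muscle myosin gene read by 1 probe set that can cross-hybridise, was higher by 3.37 ± 0.12. MAGED1 was the lowest, at -4.20 ± 0.09, followed by TEX19 at -3.85 ± 0.15, the EGF receptor ligand EREG at -3.61 ± 0.12 and MALL at -3.01 ± 0.15. SKP2, the ubiquitin ligase subunit that marks the cell cycle inhibitor p27 for degradation, was lower, at -2.97 ± 0.13, LEMD1 at -2.75 ± 0.17, NAP1L5 at -2.73 ± 0.15 and the aldo-keto reductase AKR1C1 at -2.71 ± 0.14.

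**Figure D1:**
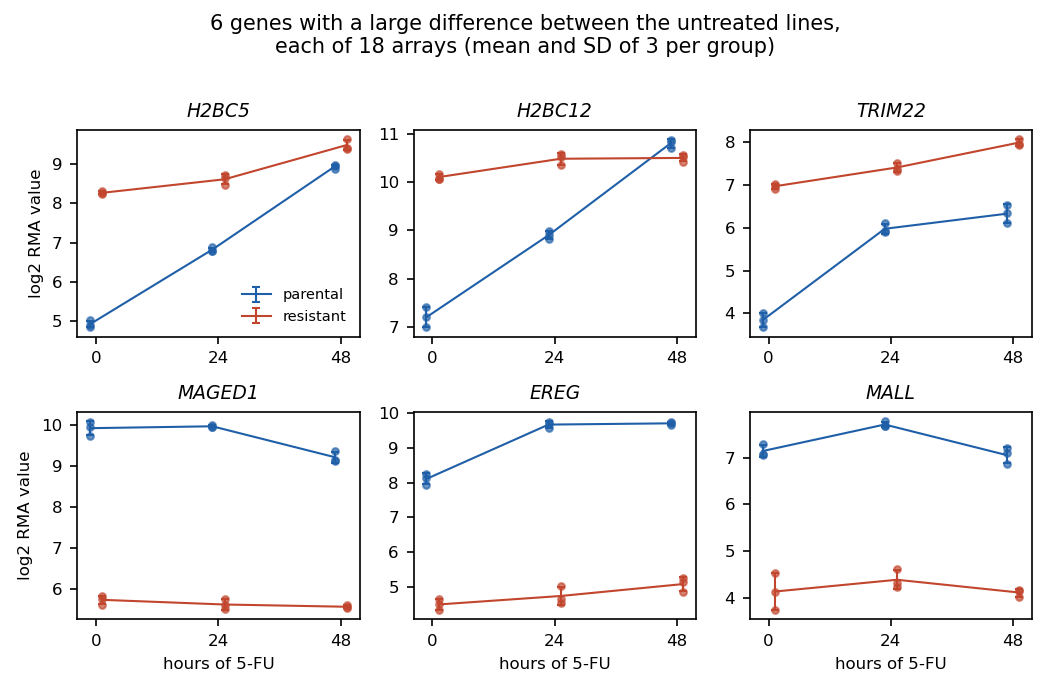
Log2 values (vertical axes) against hours of 5-FU (horizontal axes) for 6 genes with a large difference between the untreated lines; points are single arrays, lines join the means of 3 arrays and bars are SD. At 0 h all 3 resistant arrays lie above all 3 parental arrays for H2BC5, H2BC12 and TRIM22 and below them for MAGED1, EREG and MALL. The rule for named genes required this separation at 0 h.

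In all, 6437 genes passed an adjusted p of 0.05 between the untreated lines, 3236 higher and 3201 lower in the resistant line. Of these, 287 were higher and 248 lower by at least 2-fold. The 3 resistant and 3 parental arrays did not overlap for 42.4% of the genes tested, against 10% by chance.

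Integrated stress response, NRF2 and immediate early genes were lower in the untreated resistant line. Of 32 measured genes of the integrated stress response, which restrains translation and raises amino acid supply, 25 were lower, 2 higher and 5 did not pass, the same counts of 25 and 2 when adjusted over the list alone. The mTOR inhibitor DDIT4 was lower, at -2.64, DDIT3 at -1.91 and TRIB3 at -1.90, while NUPR1 was higher by 1.62. Its median was -0.65 (camera adjusted p = 1.9e-12, adjusted p = 0.040 with an estimated correlation). NRF2 targets and glutathione genes were lower in 22 of 36 members, with 2 higher and 12 not past the test (23 and 2 adjusted over the list alone). PIR was lower, at -2.54, GSTA4 at -2.18 and NQO1 at -1.66 (median -0.45, adjusted p = 1.1e-08, and adjusted p = 0.040 with an estimated correlation). Of 21 immediate early genes 14 were lower and 1 higher (15 and 1 adjusted over the list alone), among them EGR1 at -2.61 and FOS at -1.90. Its median was -0.49 (adjusted p = 7.4e-08, adjusted p = 0.053 with an estimated correlation).

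p53 targets stood higher in the resistant line at 0 h. Of 36 measured targets 22 were higher, 5 lower and 9 not past the test, with the same 22 and 5 adjusted over the list alone. TIGAR was higher by 1.90, the death receptor gene FAS by 1.85, TP53INP1 by 1.79 and ZMAT3 by 1.74 (median 0.42, adjusted p = 1.1e-06, adjusted p = 0.025 with an estimated correlation). Of 37 genes of G2/M and mitosis 18 were higher and 2 lower, led by CENPE at 1.43 and HMMR at 1.08, also when adjusted over the list alone. Its median was 0.36 (adjusted p = 0.0052, adjusted p = 0.41 with an estimated correlation). Histone genes were higher in 11 of 27 members and lower in 2, also when adjusted over the list alone. Its median was 0.08 (adjusted p = 0.00098, adjusted p = 0.073 with an estimated correlation). The method primes on poly-A tails, so histone transcripts are read only where they carry one.

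Oxidative phosphorylation, hypoxia and glycolysis, cytosolic ribosomal protein and folate cycle lists had more members lower than higher in the untreated resistant line. Of 35 oxidative phosphorylation genes 21 were lower and 2 higher by both adjustments, with SDHA at -0.93 and CYC1 at -0.88. Its median was -0.21 (adjusted p = 7.4e-07, adjusted p = 0.083 with an estimated correlation). Hypoxia and glycolysis genes were lower in 16 of 31 members and higher in 3 (18 and 3 adjusted over the list alone), including NDRG1 at -1.48 and ALDOC at -1.29. Its median was -0.27 (adjusted p = 8.6e-06, adjusted p = 0.073 with an estimated correlation). Of 46 cytosolic ribosomal protein genes 18 were lower and 0 higher (19 and 0 adjusted over the list alone), by amounts up to the -0.47 of RPS9 and -0.46 of RPL10A. Its median was -0.13 (adjusted p = 2.7e-05, adjusted p = 0.040 with an estimated correlation). With quantile normalization this list was not called (median -0.043, adjusted p = 0.12). The thymidylate and folate cycle was lower in 9 of 16 members and higher in 2 by both adjustments, with the mitochondrial serine enzyme SHMT2 at -1.05, ALDH1L1 at -1.03 and MTHFD2 at -0.90. Its median was -0.30 (adjusted p = 0.0052, adjusted p = 0.071 with an estimated correlation).

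The remaining called lists were MHC class I antigen presentation, mesenchymal genes and the BCL2 family. MHC class I antigen presentation was lower in 9 of 20 members and higher in 3, with the immunoproteasome subunit PSMB9 at -1.80. Its median was -0.14 (adjusted p = 0.0086, adjusted p = 0.33 with an estimated correlation). Mesenchymal genes were lower in 11 of 30 and higher in 2 (11 and 3 adjusted over the list alone), with AXL at -2.25 and VIM at -2.05. Its median was -0.04 (adjusted p = 0.013, adjusted p = 0.12 with an estimated correlation). The BCL2 family was lower in 9 of 20 and higher in 1, with BAK1 at -0.60 and MCL1 at -0.52. Its median was -0.15 (adjusted p = 0.016, adjusted p = 0.21 with an estimated correlation). Alu repeat signal was higher in the untreated resistant line by 0.19, beside all these groups.

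The other lists were not called between the untreated lines, and most had members called both ways. ABC drug efflux transporters had 4 of 15 members higher and 3 lower (adjusted p = 0.84), with ABCB1, the P-glycoprotein gene, higher by 0.89 ± 0.07 and ABCG2 lower, at -1.55. The genes of 5-FU uptake, activation and breakdown had 2 of 21 higher and 4 lower, with RRM2B at 1.31 and TK1 at -0.65 ± 0.09 (adjusted p = 0.71). That list's median and test lay below 0 and its mean just above, as for the 14 cancer-testis antigens (0 called, adjusted p = 0.95). The leukocyte markers, whose mean also lay above 0, had 1 of 19 higher, which was LYZ, and 3 lower (adjusted p = 0.55). Intestinal stem cell and Wnt target genes had 11 of 26 higher and 8 lower (adjusted p = 0.13), with APCDD1 at 1.93 and LRIG1 at -1.74. Interferon-stimulated genes had 7 of 37 higher and 12 lower (adjusted p = 0.28), with MX2 at 1.48 and BST2 at -2.42. Intestinal differentiation genes had 12 of 38 higher and 8 lower (adjusted p = 0.43), with the trefoil factors TFF2 at 1.79 and TFF3 at 1.68.

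Repair and death genes were also split in the untreated lines. Homologous recombination and Fanconi genes had 11 of 22 higher and 3 lower (adjusted p = 0.060), and base excision and mismatch repair 3 of 23 higher and 8 lower (adjusted p = 0.50). Death receptors and caspases had 8 of 21 higher and 3 lower (adjusted p = 0.072). G1/S and DNA replication genes had 9 of 39 higher and 10 lower (adjusted p = 0.45), and ribosome biogenesis 11 of 46 higher and 7 lower (adjusted p = 0.45). ER chaperones had 5 of 24 higher and 11 lower (adjusted p = 0.060), and autophagy and lysosome genes 12 of 32 higher and 6 lower (adjusted p = 0.086). NF-kB targets had 3 of 26 higher and 6 lower (adjusted p = 0.55). Cholesterol synthesis had 2 of 19 higher and 3 lower, epithelial junction and keratin genes 9 of 37 each way, and fibroblast and endothelial markers 2 of 19 higher and 0 lower (adjusted p = 0.45, 0.70 and 0.45). Adjusted over the list alone, these counts moved by at most 3 genes each way.

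At 24 h of 5-FU mitotic genes were higher and p53 targets lower in the resistant line. DEPDC1, a gene active in dividing cells, was higher in the resistant line by 3.74 ± 0.19, followed by NRXN3 at 3.03 ± 0.14, PHLDB2 at 2.99 ± 0.12 and SAMD4A at 2.94 ± 0.13. EREG (-4.93 ± 0.12), MAGED1 (-4.36 ± 0.09), MALL (-3.32 ± 0.15) and NAP1L5 (-2.96 ± 0.15) were lowest. G2/M and mitosis genes were higher in 31 of 37 members and lower in 0 (median 1.05, adjusted p = 9.9e-12, adjusted p = 0.096 with an estimated correlation). p53 targets, higher in the resistant line at 0 h, were now lower in 26 of 36 members and higher in 4. Among them PLK3 read -1.94 and SERTAD1 -1.81, while TRIM22 was still higher by 1.44. The median of the p53 list was -0.65 (adjusted p = 7.8e-09, adjusted p = 0.0065 with an estimated correlation). Immediate early genes were lower in 17 of 21 and higher in 1, with EGR1 at -2.75 (median -1.21, adjusted p = 5.9e-11, adjusted p = 0.042 with an estimated correlation). Ribosome biogenesis was higher in 26 of 46 members and lower in 6 (median 0.33, adjusted p = 0.10 with an estimated correlation). At this time 7907 genes passed, 4114 higher and 3793 lower in the resistant line (813 and 397 by at least 2-fold), and the arrays of the lines did not overlap for 54.5% of genes, against 10% by chance.

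At 48 h of 5-FU the lipid flippase gene ATP8A1 (3.87 ± 0.15), RAB26 (3.58 ± 0.08), LIMCH1 (3.33 ± 0.13) and the Wnt target APCDD1 (3.32 ± 0.11) were highest relative to the parental line. EREG (-4.63 ± 0.12), MAGED1 (-3.66 ± 0.09), the apolipoprotein gene APOA2 (-2.99 ± 0.14) and MALL (-2.94 ± 0.15) were lowest. Ribosome biogenesis was now lower in 30 of 46 members and higher in 1, with NOP14 at -1.11 (median -0.37, adjusted p = 4.7e-07, adjusted p = 0.12 with an estimated correlation). G2/M genes were still higher in 28 of 37 members and lower in 2 (median 0.66, adjusted p = 4.7e-07, adjusted p = 0.29 with an estimated correlation). NF-kB targets were lower in 13 of 26 and higher in 3, with the chemokine gene CXCL8 at -2.53 (median -0.29, adjusted p = 0.012, adjusted p = 0.29 with an estimated correlation). p53 targets were lower in 17 of 36 and higher in 5 (median -0.15, adjusted p = 0.038, adjusted p = 0.29 with an estimated correlation), and that list was not called with quantile normalization (median -0.091, adjusted p = 0.13). In all 8231 genes passed, 4380 higher and 3851 lower (926 and 236 by at least 2-fold), with no overlap between the lines for 52.2% of genes, against 10% by chance. Adjusted over the list alone, no list's count of higher or lower genes moved by more than 4 at 24 h or 48 h. The Alu, GAPDH, 18S and poly-A control differences between the lines stand beside these groups at every time. The ACTB values of the resistant and parental arrays overlapped at 0 h (1.82 to 2.20 and 1.51 to 1.93). They also overlapped at 24 h (1.67 to 1.84 and 1.55 to 1.78).

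In parental cells p53 targets rose and proliferation genes fell by 24 h of 5-FU. The cell adhesion gene NECTIN4 rose by 4.46 ± 0.12, the p53 targets TP53I3 by 4.22 ± 0.09, TP53INP1 by 3.29 ± 0.10 and FAS by 3.17 ± 0.14. LY6D rose by 3.61 ± 0.11, the lipase gene CEL by 3.02 ± 0.16, the transcriptional repressor gene PRDM1 by 3.01 ± 0.08 and ELAPOR1 by 2.998 ± 0.12. Falls were led by DEPDC1 at -3.11 ± 0.19, the cyclic GMP phosphodiesterase gene PDE9A at -2.73 ± 0.10, LIMCH1 at -2.67 ± 0.13 and AGPS, a gene of ether lipid synthesis, at -2.51 ± 0.13. RPL22L1 (-2.50 ± 0.07, same sign in 1 of 2 probe sets), the spindle checkpoint kinase gene BUB1B (-2.50 ± 0.09), RAB26 (-2.46 ± 0.08) and PCK2 (-2.44 ± 0.10) followed.

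Of the 36 p53 targets 35 rose at 24 h in parental cells and 0 fell, with CDKN1A, the p21 cell cycle inhibitor, up by 2.47 ± 0.07 and MDM2, the ubiquitin ligase that degrades p53, up by 2.44 ± 0.14. The list median was 1.36 (adjusted p = 6.1e-28, adjusted p = 1.7e-05 with an estimated correlation). All 37 G2/M genes fell (median -1.15, adjusted p = 1e-17, adjusted p = 0.053 with an estimated correlation). Of 39 G1/S genes 33 fell and 2 rose (median -0.63, adjusted p = 1.9e-11, adjusted p = 0.033 with an estimated correlation). The integrated stress response fell in 20 of 32 members and rose in 4 (median -1.05, adjusted p = 8.2e-09, adjusted p = 0.092 with an estimated correlation). Homologous recombination and Fanconi genes fell in 18 of 22 and rose in 1 (median -0.58, adjusted p = 0.092 with an estimated correlation). The thymidylate and folate cycle fell in 10 of 16 and rose in 2 (median -0.60, adjusted p = 0.053 with an estimated correlation). Counts adjusted over each list alone differed by at most 1 gene for these lists.

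Some NF-kB targets and intestinal differentiation genes rose in parental cells at 24 h. NF-kB targets rose in 10 of 26 members and fell in 1, with CXCL8 up by 2.06, LIF by 1.27 and IL32 by 1.19. Its median was 0.23 (adjusted p = 0.0017, adjusted p = 0.11 with an estimated correlation). Intestinal differentiation genes rose in 17 of 38 and fell in 6, with CEACAM1 up by 2.03, CEACAM6 by 1.74 and the mucin gene MUC2 by 1.70. Its median was 0.20 (adjusted p = 0.0057, adjusted p = 0.23 with an estimated correlation). Stem cell and Wnt target genes fell in 13 of 26 and rose in 2, with LGR5 at -1.82 and AXIN2 at -1.05. Its median was -0.16 (adjusted p = 0.028, adjusted p = 0.21 with an estimated correlation). In all 7960 genes passed, 3617 up and 4343 down (270 and 772 by at least 2-fold), with no overlap of the arrays for 49.0% of genes, against 10% by chance. The Alu control read 13.02 to 13.20 on the 3 parental arrays at 24 h and 13.26 to 13.42 on the 3 at 0 h.

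At 48 h cell cycle genes had fallen further in parental cells. The spindle checkpoint kinase gene BUB1 (-4.99 ± 0.12), ASPM (-4.75 ± 0.23), CENPF (-4.43 ± 0.24) and KIF20A (-4.38 ± 0.15) fell most. The topoisomerase gene TOP2A (-4.33 ± 0.19), TTK (-4.32 ± 0.17), HMGB2 (-4.30 ± 0.11) and DEPDC1B (-4.29 ± 0.13) followed. The histone genes H2BC5 (4.02 ± 0.08) and H2BC12 (3.61 ± 0.10), the gastrin gene GAST (4.01 ± 0.12) and CXCL8 (3.58 ± 0.09) were among the largest rises. So were NECTIN4 (3.94 ± 0.12), TP53I3 (3.79 ± 0.09), FAS (3.49 ± 0.14) and RPL27A (3.79 ± 0.13, from 1 probe set). All 37 G2/M genes fell (median -3.40, adjusted p = 3.6e-35, adjusted p = 0.0042 with an estimated correlation). Of 39 G1/S genes 37 fell (median -1.81, adjusted p = 0.0011 with an estimated correlation), among them DTL at -3.78 and CDC45 at -3.22. Of 22 homologous recombination genes 19 fell and 2 rose (median -1.56, adjusted p = 0.017 with an estimated correlation), with BARD1 at -3.41 and BRCA1 at -2.84. p53 targets stayed up in 32 of 36 members and fell in 1 (median 1.27, adjusted p = 2.2e-19, adjusted p = 0.00014 with an estimated correlation). The folate list fell in 11 of 16 and rose in 3, with SHMT1 at -1.72 and the dUTPase gene DUT at -1.42 (median -0.99, adjusted p = 0.019 with an estimated correlation).

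Groups outside the cell cycle also moved in parental cells at 48 h. Ribosome biogenesis rose in 28 of 46 members and fell in 9, with NOP2 at 1.23 and NOP16 at 1.18 (median 0.40, adjusted p = 0.00042, adjusted p = 0.099 with an estimated correlation). Cytosolic ribosomal protein genes fell in 18 of 46 and rose in 1 (median -0.14, adjusted p = 0.0003, adjusted p = 0.039 with an estimated correlation). The integrated stress response fell in 21 of 32 and rose in 7, led by the cystine transporter gene SLC7A11 at -3.004 and the serine synthesis gene PHGDH at -2.86. Its median was -0.97 (adjusted p = 0.11 with an estimated correlation). Epithelial junction and keratin genes rose in 21 of 37 and fell in 5 (median 0.31, adjusted p = 0.019 with an estimated correlation). Histone genes rose in 14 of 27 and fell in 2 (median 0.34, adjusted p = 0.0013, adjusted p = 0.082 with an estimated correlation). NF-kB targets rose in 15 of 26 and fell in 1 (median 0.29, adjusted p = 0.00069, adjusted p = 0.082 with an estimated correlation). In all 8828 genes passed, 4544 up and 4284 down (494 and 1132 by at least 2-fold), with no overlap for 49.9% of genes, against 10% by chance. The list counts moved by at most 2 when adjusted over the list alone. In parental cells the Alu control read 13.15 to 13.24 at 48 h, and the 18S control 11.50 to 11.56 against 11.03 to 11.46 at 0 h. The BioB hybridisation control, added after labelling, read 7.59 to 7.73 on the 6 arrays at 48 h and 7.10 to 7.31 on the 6 at 0 h. How far changes at 48 h follow a difference in hybridisation cannot be told here.

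**Figure D2:**
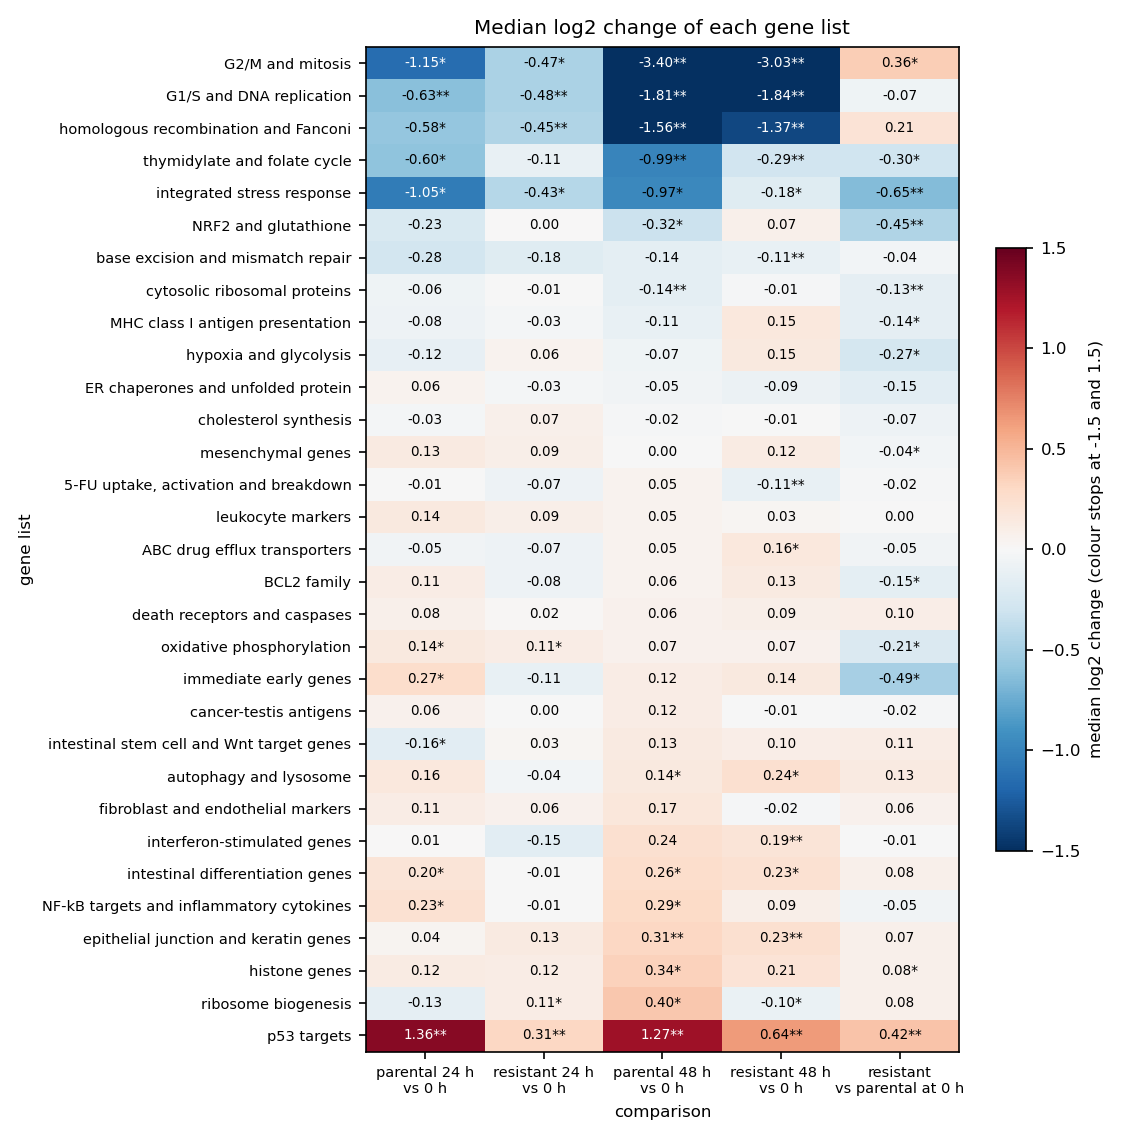
Median log2 change of 31 gene lists (vertical axis) in 5 comparisons (horizontal axis); colour stops at -1.5 and 1.5, * marks a camera adjusted p below 0.05 and ** one that also holds with an estimated correlation. G2/M genes have the lowest medians at 48 h, -3.40 in the parental and -3.03 in the resistant line, and p53 targets the highest, 1.27 and 0.64.

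From 24 h to 48 h in parental cells KIF20A (-3.63 ± 0.15), MAD2L1 (-3.53 ± 0.23), BUB1 (-3.33 ± 0.12) and the ribonucleotide reductase subunit gene RRM2 (-3.30 ± 0.10) fell most. H2AC6 rose by 2.29 ± 0.10, RPL27A by 2.21 ± 0.13, H2BC5 by 2.12 ± 0.08 and TNFRSF19 by 1.95 ± 0.09. G2/M genes fell in 37 of 37 members (median -2.37, adjusted p = 0.0017 with an estimated correlation). Ribosome biogenesis rose in 33 of 46 and fell in 2 (median 0.54, adjusted p = 6.8e-13, adjusted p = 0.0059 with an estimated correlation). Interferon-stimulated genes rose in 15 of 37 and fell in 0 (adjusted p = 0.013 with an estimated correlation). Of the 6022 genes that passed, 3396 rose and 2626 fell (114 and 234 by at least 2-fold), and the arrays did not overlap for 43.1% of genes, against 10% by chance. BioB read 7.14 to 7.30 on the parental arrays at 24 h and 7.61 to 7.71 at 48 h. List counts adjusted over the list alone differed by at most 4.

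In resistant cells p53 targets rose by 24 h of 5-FU, and cell cycle and integrated stress response genes fell. The carboxypeptidase gene CPA4 rose by 2.43 ± 0.19, the keratin-associated protein gene KRTAP3-1 by 1.88 ± 0.13, the lysyl oxidase family gene LOXL4 by 1.36 ± 0.12 and the mitochondrial thioredoxin reductase gene TXNRD2 by 1.35 ± 0.10. ANKRD1 (1.29 ± 0.14), IGFL2 (1.23 ± 0.09), CHI3L1 (1.15 ± 0.18) and GAS6-AS1 (1.14 ± 0.14) followed. Amino acid synthesis genes were among the largest falls, with PHGDH at -1.98 ± 0.09 and the asparagine synthetase gene ASNS at -1.82 ± 0.08. SRPX (-2.07 ± 0.12), TMT1A (-1.87 ± 0.12), N4BP2L1 (-1.85 ± 0.12), the oxidase gene NOX1 (-1.69 ± 0.13), NUPR1 (-1.66 ± 0.10) and the transglutaminase gene TGM2 (-1.56 ± 0.11) also fell.

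p53 targets rose in 23 of 36 members in the resistant line at 24 h and fell in 0 (28 and 1 adjusted over the list alone), with MDM2 up by 1.13 ± 0.14 and CDKN1A by 0.67 ± 0.07. Its median was 0.31 (adjusted p = 1.7e-17, adjusted p = 0.00022 with an estimated correlation). G1/S genes fell in 28 of 39 and rose in 0 (30 and 0 adjusted over the list alone, median -0.48, adjusted p = 5.4e-21, adjusted p = 0.0025 with an estimated correlation). G2/M genes fell in 24 of 37 and rose in 0 (29 and 0 adjusted over the list alone, median -0.47, adjusted p = 1e-15, adjusted p = 0.052 with an estimated correlation). Homologous recombination genes fell in 14 of 22 and rose in 0 (16 and 0 adjusted over the list alone, median -0.45, adjusted p = 0.028 with an estimated correlation). The integrated stress response fell in 21 of 32 and rose in 3 (21 and 5 adjusted over the list alone, median -0.43, adjusted p = 3e-11, adjusted p = 0.052 with an estimated correlation). Oxidative phosphorylation rose in 6 of 35 and fell in 0 (12 and 0 adjusted over the list alone, median 0.11, adjusted p = 3.3e-06, adjusted p = 0.11 with an estimated correlation).

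In all 2457 genes passed at 24 h in the resistant line, 729 up and 1728 down (12 and 53 by at least 2-fold), with no overlap for 39.0% of genes, against 10% by chance. The poly-A controls averaged 5.18 to 5.38 on the 3 resistant arrays at 24 h and 5.44 to 5.47 on the 3 at 0 h, and the Alu control 13.48 to 13.51 against 13.51 to 13.52. This count moved with the choice of arrays. Without resistant 0 h replicate 1 or 2 it was 1583 or 1518, without resistant 24 h replicate 2 or 3 it was 1605 or 1620. It was 3043 without parental 0 h replicate 2, an array outside this comparison that enters only the shared estimate of spread. A fit of the 2 compared groups alone gave 3606. The count was 3894 after correction for the main component of the deviations within groups, an alternative chosen after seeing the data.

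At 48 h the resistant cells also lost cell cycle transcripts. SPC25 (-4.08 ± 0.15), ZNF367 (-4.07 ± 0.23), ASPM (-4.02 ± 0.23) and RRM2 (-3.99 ± 0.10) fell most. BUB1 (-3.92 ± 0.12), DLGAP5 (-3.88 ± 0.18), the cohesin acetyltransferase gene ESCO2 (-3.85 ± 0.20) and MAD2L1 (-3.82 ± 0.23) followed. Rises were smaller, at 1.53 ± 0.10 for H2AC6, 1.53 ± 0.08 for the keratin gene KRT13, and 1.52 ± 0.12 for LOXL4. ANKRD1 rose by 1.39 ± 0.14, the microRNA host gene MIR22HG by 1.39 ± 0.08, and both C1orf116 and SERPINF1 by 1.32 ± 0.10. LY6D rose by 1.31 ± 0.11, with the same sign in 1 of 2 probe sets. All 37 G2/M genes fell (median -3.03, adjusted p = 7.1e-69, adjusted p = 0.0002 with an estimated correlation), and so did 38 of 39 G1/S genes (median -1.84, adjusted p = 3.9e-05 with an estimated correlation). Of 22 homologous recombination genes 18 fell and 0 rose (median -1.37, adjusted p = 0.00063 with an estimated correlation). p53 targets rose in 32 of 36 members and fell in 0, with TP53INP1 at 1.25 and GADD45A at 1.17. Its median was 0.64 (adjusted p = 1.3e-19, adjusted p = 6.6e-05 with an estimated correlation).

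Some folate, 5-FU metabolism and repair genes fell in the resistant line at 48 h. The folate list fell in 8 of 16 members and rose in 1, with TYMS, the target enzyme of 5-FU, at -1.75 ± 0.07 and MTHFD2 at -1.17. Its median was -0.29 (adjusted p = 9.4e-06, adjusted p = 0.0054 with an estimated correlation). The 5-FU metabolism list fell in 6 of 21 and rose in 1, with TK1 at -2.63 ± 0.09 and RRM1 at -2.10. Its median was -0.11 (adjusted p = 0.00041, adjusted p = 0.0065 with an estimated correlation). Base excision and mismatch repair fell in 9 of 23 and rose in 4, with EXO1 at -2.12 and NEIL3 at -1.54. Its median was -0.11 (adjusted p = 0.011, adjusted p = 0.029 with an estimated correlation). Interferon-stimulated genes rose in 16 of 37 and fell in 1, with IFI27 at 0.92 and IRF7 at 0.68 (median 0.19, adjusted p = 0.012, adjusted p = 0.024 with an estimated correlation). Epithelial junction and keratin genes rose in 18 of 37 and fell in 2 (median 0.23, adjusted p = 0.012 with an estimated correlation). Autophagy and lysosome genes rose in 18 of 32 and fell in 0, with NEU1 at 0.60 (median 0.24, adjusted p = 0.00034, adjusted p = 0.087 with an estimated correlation). In all 4959 genes passed, 3059 up and 1900 down (39 and 337 by at least 2-fold), with no overlap for 46.0% of genes, against 10% by chance. The Alu control read 13.43 to 13.46 on the resistant arrays at 48 h and 13.51 to 13.52 at 0 h. Adjusted over the list alone, the counts of the lists above moved by at most 3.

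From 24 h to 48 h in the resistant line SRPX, which had fallen by 24 h, rose by 2.09 ± 0.12, the fatty acid binding protein gene FABP1 by 2.06 ± 0.11, the annexin gene ANXA13 by 1.93 ± 0.10 and AKR1C3 by 1.86 ± 0.15. MAD2L1 (-3.85 ± 0.23), RRM2 (-3.63 ± 0.10), BUB1 (-3.45 ± 0.12) and ASPM (-3.44 ± 0.23) fell most. Ribosome biogenesis fell in 22 of 46 members and rose in 2, with GAR1 at -1.11 and TCOF1 at -0.97. Its median was -0.18 (adjusted p = 1.2e-05, adjusted p = 0.045 with an estimated correlation). Interferon-stimulated genes rose in 19 of 37 and fell in 2 (median 0.36, adjusted p = 0.00042, adjusted p = 0.0068 with an estimated correlation). Of 6732 genes that passed, 4101 rose and 2631 fell (99 and 271 by at least 2-fold), with no overlap for 53.4% of genes, against 10% by chance. From 24 h to 48 h the controls also moved, with poly-A averages of 5.18 to 5.38 and then 5.43 to 5.52, BioB at 6.98 to 7.16 and then 7.59 to 7.73, and Alu at 13.48 to 13.51 and then 13.43 to 13.46. Adjusted over the list alone, list counts differed by at most 3.

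The test of the difference between the lines' responses shows which genes changed unequally over the time in 5-FU. At 24 h the p53 targets TP53I3 (-3.34 ± 0.13), TP53INP1 (-2.65), FAS (-2.40) and CDKN1A (-1.80 ± 0.10) responded more negatively in the resistant line, as did NECTIN4 (-3.57 ± 0.18), S100A3 (-3.14 ± 0.15) and CEL (-2.82 ± 0.22). DEPDC1 (2.76 ± 0.27), ANKRD1 (2.75 ± 0.19), LIMCH1 (2.24 ± 0.18) and TEX19 (2.18 ± 0.21) differed the other way. Of 36 p53 targets 31 had a more negative change in the resistant line and 0 a more positive one (median -1.10, adjusted p = 1.6e-29, adjusted p = 1.3e-05 with an estimated correlation). G2/M genes changed more positively in the resistant line in 22 of 37 members and more negatively in 0 (median 0.59, adjusted p = 0.13 with an estimated correlation). The integrated stress response changed more positively in 19 of 32 and more negatively in 4 (median 0.38, adjusted p = 0.17 with an estimated correlation). In all 4411 genes passed at 24 h, 2487 with a more positive and 1924 with a more negative change in the resistant line (342 and 221 by at least 2-fold).

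**Figure D3:**
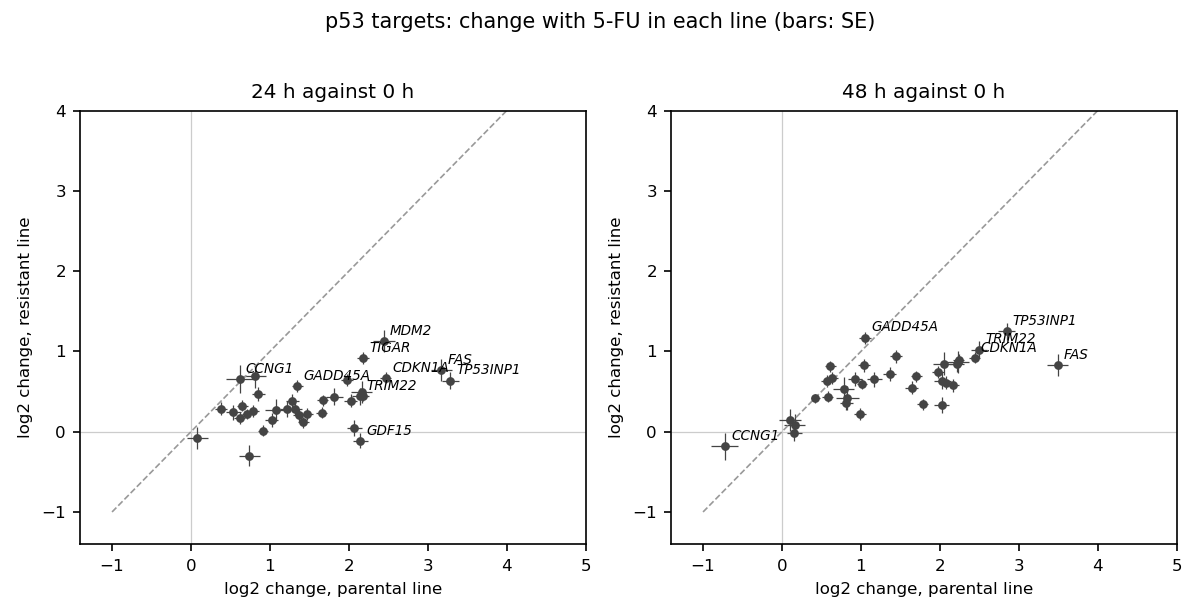
Log2 change with 5-FU of the 36 measured p53 targets in the parental line (horizontal axis) and the resistant line (vertical axis) at 24 h (left) and 48 h (right); bars are SE, from 3 arrays per group, and the dashed line marks equal changes. Most points lie below the line, as for CDKN1A, with 2.47 in the parental and 0.67 in the resistant line at 24 h.

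At 48 h LIMCH1 (3.23 ± 0.18), ANKRD1 (3.01 ± 0.19), PDE9A (3.01 ± 0.15) and RAB26 (2.98 ± 0.11) changed more positively in the resistant line, and RPL27A (-3.56 ± 0.18), NECTIN4 (-3.33 ± 0.18), H2BC12 (-3.21 ± 0.14) and TP53I3 (-3.06 ± 0.13) more negatively. p53 targets still had a more negative change in 22 of 36 members and a more positive one in 0 (median -0.58, adjusted p = 2.1e-11, adjusted p = 0.0016 with an estimated correlation). Ribosome biogenesis changed more negatively in 28 of 46 and more positively in 1 (median -0.51, adjusted p = 1.4e-08, adjusted p = 0.040 with an estimated correlation). NRF2 and glutathione genes changed more positively in the resistant line in 21 of 36 members and more negatively in 2, with SLC7A11 at 2.62, PIR at 2.23 and AKR1C1 at 2.03. Its median was 0.41 (adjusted p = 1.8e-06, adjusted p = 0.10 with an estimated correlation). In all 5735 genes passed at 48 h, 3302 more positive and 2433 more negative (757 and 267 by at least 2-fold). List counts adjusted over the list alone differed by at most 6 at 24 h and 5 at 48 h.

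Both lines shared much of the direction of change. Of 729 genes that rose at 24 h in the resistant line 453 also rose in the parental line, where 145 would be shared if the calls were independent, and 49 fell. Of 1728 that fell 1292 fell in both, with 414 in the independent case, and 99 rose in the parental line. At 48 h 1703 of 3059 rises (767 in the independent case) and 1264 of 1900 falls (449) were shared, with 513 and 88 called the opposite way. The BioB control was higher at 48 h in both lines. How far a difference in hybridisation adds to the sharing at 48 h cannot be told here. The correlation of the changes across genes, which are not independent replicates, was r = 0.55 at 24 h and 0.62 at 48 h. The median absolute change was 0.22 and 0.25 in the parental line and 0.12 and 0.16 in the resistant line.

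Among genes named in advance for 5-FU handling, TYMS, TK1 and RRM2 fell in both lines by 48 h. UMPS, UPP1 and TYMP changed less with time and read lower in the resistant line at 48 h. TK1 also differed between the lines at 24 h, with 9.01 to 9.07 on the resistant and 10.06 to 10.10 on the parental arrays. TYMS was 0.38 ± 0.07 higher in the untreated resistant line (adjusted p = 0.00028). At 48 h it had fallen against 0 h, at -0.76 ± 0.07 in parental and -1.75 ± 0.07 in resistant cells (difference -0.995, adjusted p = 5.2e-07). UMPS, which converts 5-FU to its nucleotide, rose in parental cells by 0.48 at 24 h and 0.65 at 48 h, and its 48 h response was lower in resistant cells (difference -0.88, adjusted p = 2.1e-06). In parental cells at 48 h RRM2 (-3.51 ± 0.10) and TK1 (-2.19 ± 0.09) fell. DPYD, the enzyme that degrades 5-FU, read 1.99 to 2.74 on the 18 arrays, below the 25th percentile of the probe sets (2.97 to 3.09). It passed in no comparison (0.08 ± 0.15 between the untreated lines, adjusted p = 0.75), which at this signal says little about its transcript. UPP1 was lower in the resistant line at 48 h (-0.29, adjusted p = 0.002).

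Some calls among these genes were near the threshold. TYMS read 0.21 in parental cells at 24 h (adjusted p = 0.021), but did not pass without parental 0 h replicate 1 or 2 (0.19 each) or 24 h replicate 1 (0.21) or 3 (0.18). TYMP, which also converts 5-FU, read 0.33 there (adjusted p = 0.0097) and did not pass without parental 0 h replicate 2 (0.26) or 24 h replicate 1 (0.27). Between the lines TYMP was lower in resistant cells at 24 h (-0.39) and 48 h (-0.45), but not past the test as the mean of its 3 probe sets (-0.16 and -0.18). UMPS read -0.23 in resistant cells at 48 h (adjusted p = 0.019) and did not pass without 0 h replicate 1 (-0.21) or 2 (-0.23) or 48 h replicate 1 (-0.205) or 3 (-0.22).

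CDKN1A and MDM2 were higher in the untreated resistant line by 0.91 ± 0.07 and 1.41 ± 0.14. At 24 h of 5-FU CDKN1A was lower there, at -0.89 ± 0.07, and MDM2 read 0.09 ± 0.14 (adjusted p = 0.64) with the probe set used but -0.39 as the mean of its 11 probe sets. RRM2 at 24 h likewise read -0.18 ± 0.10 between the lines (adjusted p = 0.18) but 0.40 as the mean of its 2 probe sets. ABCB1 was higher in the resistant line at every time, by 1.48 ± 0.07 at 24 h and 1.43 ± 0.07 at 48 h. Its change of -0.82 ± 0.07 in parental cells at 24 h had the same sign in 2 of 4 probe sets.

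**Figure D4:**
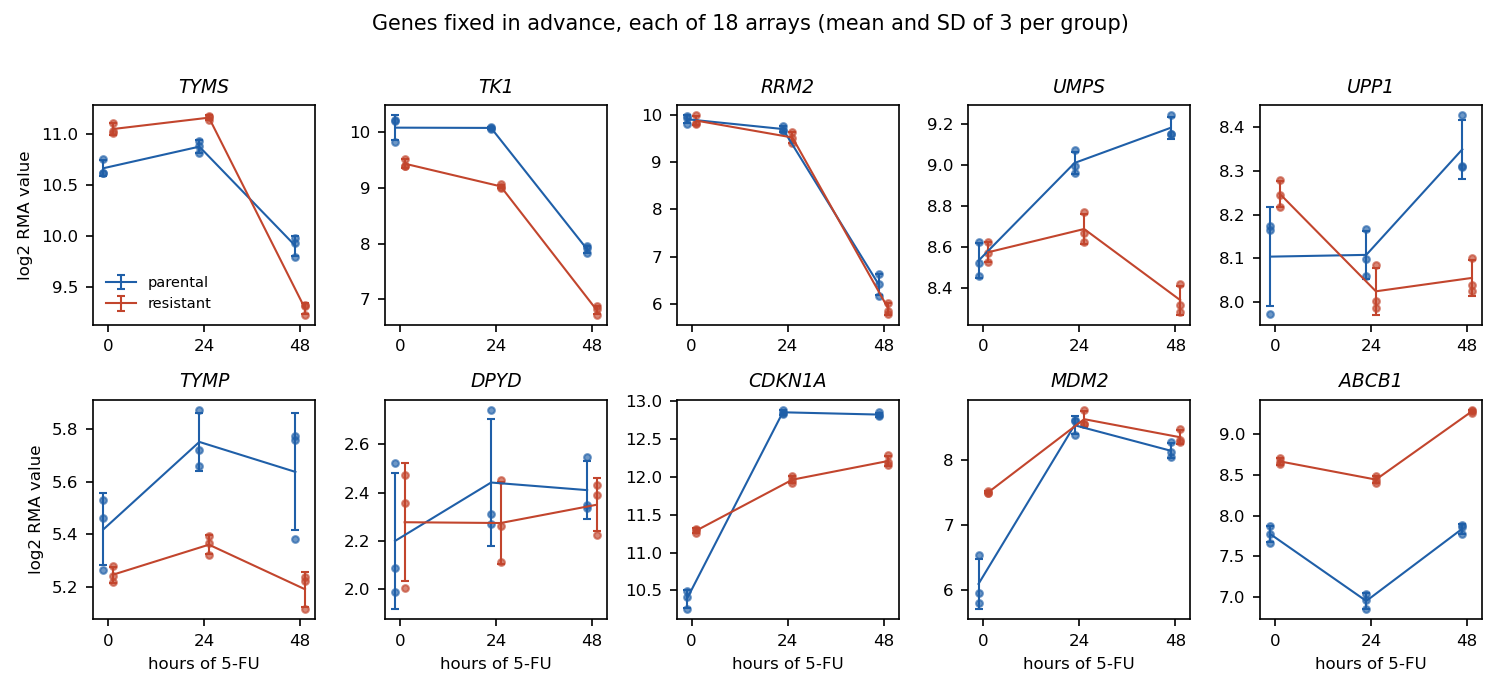
Log2 values (vertical axes) against hours of 5-FU (horizontal axes) for the 10 genes fixed in advance; points are single arrays, lines join the means of 3 arrays per group and bars are SD. RRM2 falls steeply between 24 h and 48 h in both lines, a change of -3.30 in the parental and -3.63 in the resistant line, and CDKN1A rises more in the parental line.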

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

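The counts over other splits of the arrays were planned, while taking out the lines' mean difference before relabelling and the tests of explanations for the p53 targets and for parental 0 h replicate 2 were tests chosen only after the result was seen.

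The lines' changes over the time in 5-FU differed by the test of the difference for 4411 genes at 24 h and 5735 at 48 h. The planned relabelling of the lines within each time mixes lines that differ in many genes, so it does not decide. Its highest other count at 24 h was 4309, below the real 4411. At 48 h its highest other counts were 8276 and 6085, above the real 5735. With the lines' mean difference taken out first, 1 of 100 drawn relabellings at each time gave as many genes, the real one, with highest others of 907 at 24 h and 1378 at 48 h. This version was chosen after the result was seen and leaves the difference of responses itself in the mixed groups. That widens their spread and favours the real labelling, so chance is not excluded for either count.

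For the 9 counts between 2 groups, the 10 splits of 6 arrays are too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real counts were 6437, 7907 and 8231 between the lines at 0, 24 and 48 h, 7960 and 8828 in the parental and 2457 and 4959 in the resistant line at 24 and 48 h against 0 h, and 6022 and 6732 from 24 h to 48 h. The highest of the other splits was 1 gene for parental cells from 24 h to 48 h and 0 elsewhere. A mixed split puts the difference between the groups into the spread, which lowers its count. The low counts of the other splits therefore do not decide about chance.

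p53 targets rose less in the resistant line at 24 h, with a median difference of responses of -1.10 over 36 genes. A signal ceiling from the higher starting level would put both lines at the same level at 24 h, but the resistant line was lower, with a median of -0.65. The difference also did not rest on parental 0 h replicate 2, since it was -1.05 without that array. It was -1.05 as well after the component of the dim genes was taken out, which argues against RNA or labelling differences along that component as the whole cause. A weaker p53 response in resistant cells may be the reason, as a hypothesis, while less 5-FU reaching its targets in that line could give the same values and was not tested.

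Among parental 0 h arrays, replicate 2 stood apart, with an SD of 0.275 across genes in its deviation from the other replicates against 0.212 and 0.187 for replicates 1 and 3. Its Alu (13.42), ACTB (1.93) and 18S (11.03) controls were nearest the resistant arrays among the 3. Its poly-A average (6.08) and GAPDH difference (0.019, against 0.017 and -0.031 for replicates 1 and 3) were the farthest. The difference of replicate 2 from replicate 1 or 3 went with the resistant line minus the remaining replicate (r = 0.42 and 0.33 across genes, which are not independent replicates). Resistant cells mixed into that culture would do the same but would also raise the genes at least 2.5 log2 units higher in the resistant line, and the median deviation of these 8 genes was -0.065 (range -0.31 to 0.63), with H2BC12 at -0.31 and H2BC5 at -0.04. RNA length or labelling is a candidate explanation that stays open. The deviation ranked with the genomic span of 18112 genes at rho = 0.25, but arrays of other groups reached -0.195 and 0.17. Genomic span is also not the length of the RNA, so this rank correlation cannot decide that explanation. No biological explanation was tested.

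By the list test of the difference at 24 h, further medians in the resistant minus the parental response were 0.36 for the folate cycle, 0.16 for G1/S, 0.59 for G2/M, 0.38 for the integrated stress response, 0.35 for ribosome biogenesis, 0.18 for stem cell and Wnt targets and 0.074 for cytosolic ribosomal proteins. They were -0.12 for the BCL2 family, -0.17 for NF-kB targets, -0.20 for intestinal differentiation, -0.19 for autophagy and lysosome and -0.37 for immediate early genes, and of all these lists only p53 targets held with an estimated correlation at 24 h. At 48 h the medians were -0.58 for p53 targets, -0.51 for ribosome biogenesis, -0.22 for histone genes, -0.24 for NF-kB targets, 0.49 for G2/M, 0.41 for NRF2 and glutathione, 0.47 for the integrated stress response, 0.14 for cytosolic ribosomal proteins and 0.23 for hypoxia and glycolysis, and p53 targets and ribosome biogenesis held.

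Single genes with the largest difference of responses were DEPDC1 at 2.76, ANKRD1 at 2.75, LIMCH1 at 2.24, TEX19 at 2.18, NECTIN4 at -3.57, TP53I3 at -3.34, S100A3 at -3.14 and CEL at -2.82 at 24 h. At 48 h they were LIMCH1 at 3.23, ANKRD1 at 3.01, PDE9A at 3.01, RAB26 at 2.98, RPL27A at -3.56, NECTIN4 at -3.33, H2BC12 at -3.21 and TP53I3 at -3.06.

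Control probe sets outside the gene tests also differed. The Alu control was 0.19 higher in the untreated resistant than in the untreated parental arrays, and the BioB hybridisation control was 0.42 higher on the 6 arrays at 48 h than on the 6 at 0 h.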

How the results depend on the processing

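The correction for the component of the dim genes and the list tests without parental 0 h replicate 2 were tests chosen only after the result was seen. Centring, quantile normalization, either filter on dim genes, the mean of all probe sets, each probe set alone, the compared groups alone and eBayes with trend and robust left all 11 gene counts within 1.5 times. An adjusted p below 0.01 gave 1268 and 3159 genes in the resistant line at 24 h and 48 h and 2834 for the difference at 24 h, since the threshold is stricter. The component correction gave 3894 genes in the resistant line at 24 h (reported count 2457), and the cause was not tested. Quantile normalization put 39.7% of the genes called there on the rising side, against 29.7%.

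Counts of at least 2-fold were lower with the mean of all probe sets. Between the lines they were 338, 674 and 626 at 0, 24 and 48 h, against 535, 1210 and 1162. They were 557 against 1042 in parental cells at 24 h, 1074 against 1626 there at 48 h, 31 against 65 in resistant cells at 24 h, and 291 against 563 and 558 against 1024 for the differences at 24 h and 48 h. Their larger direction turned for the difference at 24 h (140 more positive and 151 more negative) and for the untreated lines (160 higher and 178 lower, and 268 and 273 with arrays centred). The cause was not tested.

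Which direction held more genes depended on the processing in 7 comparisons, and the cause was not tested. With arrays centred on the median, more genes were lower than higher in the resistant line, with 2883 higher and 3485 lower at 0 h, 3879 and 4099 at 24 h, and 4007 and 4771 at 48 h. The mean of all probe sets also gave more lower genes, with 3012 and 3148, 3594 and 3956, and 3804 and 4225. It gave 3893 up and 3834 down in parental cells at 24 h, and 1971 more positive and 2044 more negative for the difference at 24 h. Parental cells at 48 h turned to more falls than rises when the lowest 25% of genes were left out (3973 up and 4242 down). From 24 h to 48 h parental cells did so with quantile normalization (2932 and 2943). The near-even counts for the untreated lines and for parental cells at 48 h also turned under other alternatives.

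Without 1 array of the compared groups, counts for the resistant line at 24 h ran from 1518 (without 0 h replicate 2) to 1816 (without 0 h replicate 3), while the other 10 comparisons stayed within 1.5 times. Without parental 0 h replicate 2, which is outside that comparison, the count rose to 3043, and all 2457 reported genes were among them. That array does not enter the estimated changes of this comparison, only the estimate of spread shared by the groups. A fit of the 2 compared groups alone called 3606 genes. Such fits also raised the resistant counts at 48 h, to 5776 against 0 h and 7808 against 24 h. They lowered the parental counts to 6541 at 24 h, 6909 at 48 h and 4954 from 24 h to 48 h. Between the lines they gave 5210, 8305 and 7590 at 0, 24 and 48 h. The gap between the parental and resistant counts thus depends in part on the shared estimate of spread. The ERCC spike-in scaling was not run, because no ERCC probe set is among the values. With the replicate block the counts were 6346, 7834 and 8107 between the lines at 0, 24 and 48 h, 7836, 8710 and 5864 in parental cells, 2293, 4814 and 6614 in resistant cells, and 4302 and 5579 for the differences. Of 45 pairs of deviations with the same number, 8 correlated above 0.1 (median r = 0.016 across genes), so the numbers were not taken as pairs.

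The gene list tests gave 130 calls, 48 with an estimated correlation, 264 by fry, which poses another question, and 137 without parental 0 h replicate 2. Of the list results, 9 lost and 12 gained a call with quantile normalization, 4 and 7 with the component correction, 2 and 9 without parental 0 h replicate 2, and 1 and 0 with arrays centred. Quantile normalization ended the calls of cytosolic ribosomal proteins (adjusted p = 0.12 between the untreated lines, 0.19 in parental cells from 24 h to 48 h and 0.14 for the difference at 24 h) and of G1/S for that difference (0.061). It also ended those of oxidative phosphorylation in parental cells at 24 h (0.062), MHC class I between the lines at 24 h (0.057), and p53 targets (0.13), homologous recombination (0.11) and oxidative phosphorylation (0.11) between the lines at 48 h. G2/M for the difference at 48 h was not called with the component correction (0.077) or without parental 0 h replicate 2 (0.060). The cause was not tested. As the mean of all probe sets, RRM2 between the lines at 24 h read 0.40, MDM2 between the lines -0.39 at 24 h and -0.22 at 48 h, and MDM2 in parental cells from 24 h to 48 h 0.018, each reversed from the probe set used, and the cause was not tested. Of 331 values of named genes, 9 lost and 5 gained a call with the mean of all probe sets, 4 and 3 with quantile normalization, and 3 and 2 in a fit of the compared groups alone. The method gives no count behind a value, so dim genes are limited by signal over background.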

Other observations

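The tests of overlap between the late parental response and the untreated resistant line were chosen only after the result was seen.

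Some genes changed strongly in parental cells while their lists did not. LAPTM5, a lysosomal membrane gene of the leukocyte list, rose in parental cells by 2.90 at 24 h and 2.74 at 48 h and by 0.47 at 48 h in the resistant line, a difference of -2.81 at 24 h. Only a few leukocyte markers moved with it in parental cells at 24 h (3 of 19 rose and 1 fell, camera adjusted p = 0.099). ISG15, an interferon-stimulated gene, rose by 1.54 in parental cells at 24 h while BST2 read -1.58 and IFITM1 -1.20, and that list had 7 of 37 members up and 12 down with a median of 0.01, a mean of -0.18 and a test pointing down (adjusted p = 0.38). The hypoxia genes VEGFA (-1.91) and PDK1 (-1.84) fell in parental cells at 24 h, in a list with 13 of 31 members down and 6 up (adjusted p = 0.13). ACTA2, on the fibroblast list, rose by 1.74, and the cholesterol regulator gene INSIG1 fell, at -1.36.

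In the resistant line further genes rose between 24 h and 48 h. NUPR1 rose by 1.47 and DDIT4 by 0.71 after NUPR1 had fallen at 24 h, and the integrated stress response had 17 of 32 members up and 7 down in this interval (adjusted p = 0.081). The aldo-keto reductase genes AKR1B10 (1.12) and AKR1C2 (0.98) rose, in a list with 15 of 36 members up and 5 down (adjusted p = 0.067). Intestinal differentiation genes rose in 18 of 38 members and fell in 3, with CDHR5 at 0.85 and LGALS4 at 0.73 (median 0.22, adjusted p = 0.0042, adjusted p = 0.18 with an estimated correlation). ABC transporters rose in 7 of 15 members and fell in 1, with ABCC3 at 1.38 and ABCA3 at 0.76 (median 0.33, adjusted p = 0.017, adjusted p = 0.045 with an estimated correlation).

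Genes that rose in parental cells by 48 h of 5-FU tended to be higher in untreated resistant cells, as H2BC5, H2BC12 and TRIM22 were. The covariance of these changes across genes was 0.0596, but both comparisons subtract the same parental 0 h arrays, which alone gave 0.0116 in 100 simulations. With separate parental arrays and replicate 2 left out it was 0.0436 and 0.0586, so the shared arrays do not account for all of it. In the comparison of parental cells at 48 h with 24 h, which shares no array with the untreated lines, 114 genes rose at least 2-fold and 74 of them were higher in untreated resistant cells (20.3 if the calls were independent) while 4 were lower (20.1). The falls were not shared in this way, since of 234 genes that fell at least 2-fold 53 were lower in untreated resistant cells (41.3) and 74 higher (41.8). Part of the late rises may thus already be on in untreated resistant cells, which is a hypothesis from the same data, and drug carried over from selection was not tested.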
